A study of Rattus norvegicus with 8 samples.

How the data were processed

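Genomic DNA of 8 malignant peritoneal mesotheliomas was compared with DNA of non-neoplastic kidney by array comparative genomic hybridisation, which measures relative DNA copy number at each probe. Each tumour was hybridised on 1 two-colour Agilent rat array, with kidney DNA in Cy3 and tumour DNA in Cy5 per the labels. The animals were F1 hybrids of the Brown-Norway and Fischer344 strains, and 4 tumours came from females and 4 from males. The kidney DNA had the sex of the tumour's animal per the labels. Whether it came from the same animal is not given in the sources used here.

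The deposited table held 1 log2 ratio per probe and array for 174012 probes. Per the submitters' processing notes, the scanner images were processed with Agilent Feature Extraction 10.7. The background correction, dye normalization, filters and centring behind the deposited log2 ratios are not given in the sources used here. The base of the logarithm is not stated either. It was taken as 2 because the highest value, 8.78, would lie beyond a scanner's range as a base-10 logarithm. The direction is likewise unstated. It was taken as tumour over kidney from the dyes in the labels. All 28 pairs of arrays correlated positively across probes (r from 0.235 to 0.597), which a bias of the probes shared by the arrays could also give, so the orientation of each array rests on the labels. The column medians lay between -0.0167 and 0.0198. No scanner files were used here, so signal over background and batches could not be examined. The spread of single probes on the arrays, as a robust SD, was 0.169 to 0.219 on the log2 scale in 7 tumours and 0.506 in female tumour 1.

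Probes carried a feature number on the array and no gene name or genome position, and no table used here pairs them. All tests planned for genes were therefore run on probes. Probes of 1 altered region are not independent, so a number of probes is not a number of regions. The following planned steps were not run for lack of positions or names: gene summaries and probe minimums per gene, segmentation, the noise of neighbouring genes as a threshold, chromosome means, removal of the sex chromosomes, GC correction, tests of gene lists and values of named genes, Cdkn2a and Cdkn2b included. The planned random shift of calls along the genome was replaced by an independent shuffle of the probes of each array, which also breaks up neighbouring probes and so gives a narrower range of chance counts than a shift would. The feature numbers follow rows of 170 features on the array surface, where the residuals of probes correlated most. They were used to look for surface blemishes.

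7 probes listed at exactly 0 on all 8 arrays were left out after the data were examined, which left 174005. Single values listed at 0 numbered 21 to 165 per array and were kept. Each array was centred on the median of its log2 ratios. Peaks of the density of ratios were kept when they reached 2% of the highest peak and were parted by a valley at least 10% below the lower peak. A probe was called lost at or below -0.3, gained at or above 0.3 and deeply lost at or below -1.0. Recurrence meant the same call in at least 4 of 8 tumours and was set beside 100 shuffles. The mean ratio of the 8 tumours was tested against 0, and female against male tumours, with limma 3.58.1 in R 4.3.3 (two-sided, Benjamini-Hochberg adjusted p under 0.05). The test against 0 leaves out the spread of the kidney reference. Shares of probes per tumour were compared between sexes with a two-sided exact permutation test over 70 arrangements, whose smallest p is 0.029. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

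2 shared sets of probes were defined after the data were examined. Each was read only in the tumour left out of its definition. The shared deep loss set held probes at or below -1.0 in at least 4 of the other 7 tumours, and the shared gain set held probes at or above 0.5 in at least 4 of the other 7. A tumour was said to carry a set when the median of its probes passed the same threshold there.

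The limma step was tested on simulated data with the spread of each real probe and 200 shifted probes. In the test against 0 over 174005 probes, 73.1% of probes shifted by 0.5, 98.5% of those shifted by 1 and 100% of those shifted by 2 were recovered. In the comparison of sexes over 174005 probes, the recovered shares were 10.4%, 71.6% and 95.5%. Unshifted probes called in error numbered 8 in the test against 0 and 7 in the comparison of sexes. The simulated probes varied independently and few were shifted, unlike in the real data. The recovered shares therefore do not measure the power of the tests there. The number of arrays limits the precision. The labels name 8 tumours but do not state that each came from a separate animal, so p-values measure the spread between these tumours.

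The rule fixed for named items asked for the 10 lowest and 10 highest means with 1 sign in all 8 tumours, and for the 2 smallest p-values between sexes if none passed. Probes without gene names are given by number for the first 2 on each side only. Alternatives fixed before the data were examined were the deposited centring, centring on the mode of each array, array weights, robust empirical Bayes, a difference of at least 0.1, other thresholds for calls and recurrence, a count at the smallest exact permutation p, and each tumour left out in turn. The labels' protocols say that animals received saline or nitrilotriacetate, an iron chelator, but not which animal received which, so these treatments were not compared.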

Results

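The series profiled DNA copy number in malignant peritoneal mesotheliomas, tumours of the lining of the abdominal cavity, induced in rats with tremolite, an amphibole asbestos. Per the labels, F1 hybrid rats received 10 mg of tremolite in the abdominal cavity, as 2 injections of 5 mg in weeks 6 and 7. From week 10 to week 21 they received saline or nitrilotriacetate at 80 mg/kg once a week, for 12 weeks. 8 tumours were measured, 4 from females and 4 from males, each on 1 array against non-neoplastic kidney DNA. After centring, 174005 probes gave a log2 ratio, taken as tumour over kidney. A negative ratio therefore stands for fewer copies in the tumour, if the usual orientation of the dyes was kept. With the ratio turned, every loss described would be a gain and every gain a loss.

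The first question was which parts of the genome were lost or gained in these tumours, and how much. In 7 of the 8 tumours the rule for peaks kept a single peak within 0.03 of 0, with tails on both sides. The rule drops smaller rises of the density, such as those near 1.57 in male tumour 4 and near -0.57 in female tumour 2. Female tumour 1 differed from the other 7 tumours. Its probes fell into 3 peaks at log2 ratios of -0.95, -0.25 and 0.49, which held 5.63%, 47.9% and 46.4% of probes. On average 10.9% ± 5.41 of probes were lost and 10.1% ± 9.49 were gained per tumour (SD, n = 8). Female tumour 1 had 23.7% of probes lost and 33.2% gained. In the other 7 tumours, lost probes made up 6.89% to 11.5% and gained probes 3.86% to 8.72%, and the lowest shares of both were in male tumour 2. The robust SD of single probes in these 7 tumours was 0.169 to 0.219. Noise of single probes alone can therefore pass the call threshold of 0.3. What part of these shares is noise was not measured, so they are not shares of the genome altered. Without female tumour 1 the mean share gained was 6.75%.

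The values of female tumour 1 depended on where its array was centred. Its median lay between 2 peaks, and its mode was at -0.264 as deposited. With the mode set to 0, its lost share was 7.97% and its gained share 47.3%.

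**Figure D1:**
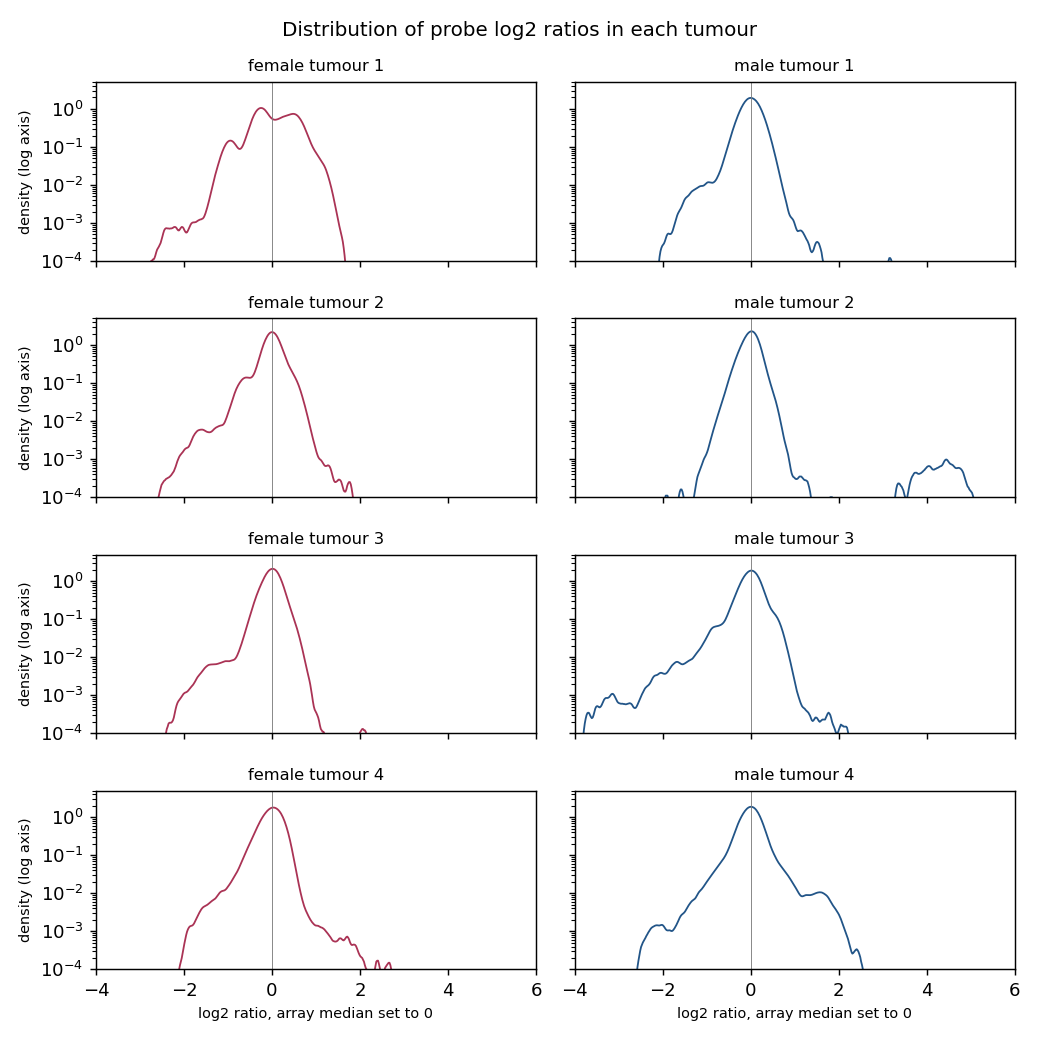
Density of probe log2 ratios (horizontal axis, array median set to 0) in each of the 8 tumours, on a logarithmic vertical axis; red lines are female tumours and blue lines male tumours; values above 6 lie outside the plot. Female tumour 1 has 3 peaks at -0.95, -0.25 and 0.49, while the rule for peaks kept 1 peak near 0 in the other 7 tumours. Smaller rises outside that rule lie near 1.57 in male tumour 4 and near -0.57 in female tumour 2. Male tumour 2 has a separate small group of probes above 3.

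Recurrent losses and gains were then counted to find regions altered in several tumours. 11726 probes (6.74%) were lost in at least 4 of 8 tumours and 7957 (4.57%) were gained in at least 4. Shuffling the probes of each array gave at most 1091 and 626. The shuffle also removes any probe bias that the arrays share. Counts above it can therefore come from such a bias as well as from recurrent copy number change. 533 probes were lost in all 8 tumours and 187 were gained in all 8. Leaving out female tumour 1 lowered the recurrently gained probes to 5037, and these counts moved by over 1.5 times with the thresholds for a call. At 0.5 on the log2 scale they were 2679 lost and 952 gained.

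Deep losses were concentrated in the same probes in most tumours. 782 probes were at or below -1.0 in at least 4 tumours, and 100 shuffles gave at most 1. 240 of them were at or below -1.0 in at least 6 tumours. In 5 of the 6 tumours with a shared loss, from 786 to 1038 probes were deeply lost, and male tumour 3 had 2073. Female tumour 3 shared 807 of its 869 deeply lost probes with male tumour 3, where 10.4 would overlap if the calls were independent. This was the closest of the 28 pairs, with 92.9% of the smaller list shared. Pairs among female tumours 2, 3 and 4 and male tumours 1, 3 and 4 shared at least 43.4% of the smaller list, the lowest being female tumour 2 with male tumour 4. Female tumour 1 shared 3.76% to 6.23% with each of these 6. Male tumour 2 had 41 deeply lost probes and shared 14.6% to 58.5% of them with the other tumours.

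The shared deep loss set, defined in the other 7 tumours and read in the tumour left out, was present in 6 tumours. Its median log2 ratio was -1.82 in male tumour 3, which is a ratio of 0.283. The medians were -1.42 in female tumour 2 and -1.38 in female tumour 3. They were -1.19 in male tumour 1, -1.15 in female tumour 4 and -1.13 in male tumour 4. In female tumour 1 and male tumour 2 the set had a median of -0.19, a ratio of 0.875 and 0.878. With the mode of its array set to 0, the median of female tumour 1 was 0.06. The upper quartile of the set reached -1.54 in male tumour 3, -0.94 in male tumour 4 and 0.24 in female tumour 1. The sets held 531 to 775 probes. With -1.5 used both to define a new set and to read it, 3 tumours carried that set.

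**Figure D2:**
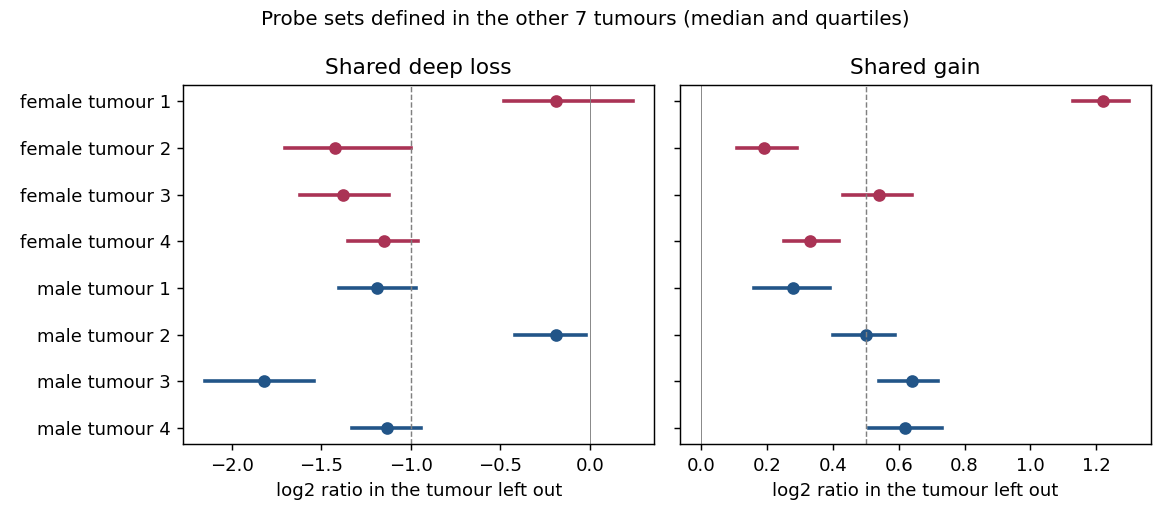
Log2 ratio (horizontal axis) of 2 probe sets in each tumour (vertical axis), where each set was defined in the other 7 tumours; points are medians over probes, lines run from the lower to the upper quartile, dashed lines mark the thresholds of -1.0 and 0.5, and red and blue stand for female and male tumours. The deep loss set lies between -1.82 and -1.13 in 6 tumours and at -0.19 in female tumour 1 and male tumour 2, and the gain set ranges from 0.19 in female tumour 2 to 1.22 in female tumour 1.

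A gain set, defined in the same way at the lower threshold of 0.5, had a median of 1.22 in female tumour 1, 0.64 in male tumour 3, 0.62 in male tumour 4 and 0.54 in female tumour 3. The median was just under the threshold, at 0.5 after rounding, in male tumour 2. It was 0.33 in female tumour 4, 0.28 in male tumour 1 and 0.19 in female tumour 2. 4 tumours thus carried the set at the threshold. When each other tumour was left out in turn, 3 to 5 of the remaining 7 carried it.

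Large gains differed between tumours. Female tumour 1 had 2185 probes at or above 1, and 8298 with its mode set to 0. Male tumour 2 had 145 probes at or above 3, with a median log2 ratio of 4.3, or 19.7 times the kidney signal. The same probes had a median of -0.55 in female tumour 2 and -0.29 in female tumour 1, and lay between -0.14 and 0.03 in the other 5 tumours. None of the 145 probes reached 1 in another tumour. Male tumour 4 had 1569 probes at or above 1, of which 1544 reached 1 in no other tumour. Their median was 1.47 in male tumour 4, where they were selected, 0.52 in female tumour 1, 0.27 in female tumour 2 and at most 0.1 in the others. The value in female tumour 1 lay close to its upper density peak of 0.49, which held 46.4% of its probes.

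The mean ratio over all 8 tumours was tested to find probes shifted in 1 direction on average, which need not hold in every tumour. With limma, 25923 probes had a mean below 0 and 24694 a mean above 0 at an adjusted p under 0.05. 17296 of the lower and 16912 of the higher probes had the same sign in all 8 tumours. Most shifts were small, with a median mean of -0.267 for the lower and 0.257 for the higher probes. 2205 probes had a mean at or below -0.5 and 845 a mean at or above 0.5. The lowest mean with 1 sign in all 8 tumours was that of probe 24591, at -1.82 ± 0.7 (SD, n = 8; limma adjusted p = 0.000566). Probe 7367 followed at -1.7 ± 0.823 (SD, n = 8; limma adjusted p = 0.00101). On the higher side, probe 88760 had a mean of 1.12 ± 0.367 (SD, n = 8; limma adjusted p = 0.000373) and probe 98060 a mean of 0.866 ± 0.419 (SD, n = 8; limma adjusted p = 0.00118). At the threshold of 0.3, 35.6% of these probes were lost or gained in the same direction in at least 4 tumours, and at 0.2 it was 76.8%.

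Female and male tumours were compared because sex was the only attribute of the animals that differed between labels. The shared deep loss was present in 3 of 4 female and 3 of 4 male tumours (two-sided Fisher's exact p = 1). With 6 carriers among 8 tumours, no arrangement by sex could bring this Fisher's test under 0.05, so it decides nothing. A set needed at least 4 of the other 7 tumours, of which only 3 have the sex of the tumour left out. A change confined to 1 sex could therefore not enter the set read in a tumour of that sex. The median of the deep loss set averaged -1.03 ± 0.57 in females and -1.08 ± 0.67 in males (SD, n = 4 each; exact permutation p = 0.943). The shared gain was carried by 2 female and 2 male tumours, with mean medians of 0.57 ± 0.46 and 0.51 ± 0.17 (SD, n = 4 each; exact permutation p = 0.914). Lost probes made up 12.9% ± 7.34 in females and 8.8% ± 1.76 in males (SD, n = 4 each; exact permutation p = 0.371, adjusted over 3 shares 0.629). Gained probes made up 13.2% ± 13.4 in females and 6.92% ± 2.19 in males (exact permutation p = 0.629, adjusted 0.629). Deeply lost probes made up 0.979% ± 0.861 and 0.564% ± 0.483 (exact permutation p = 0.514, adjusted 0.629). None of these differences passed its test, but for the 2 sets their definition limits what a comparison of sexes could find. The differences in the 3 shares depended on female tumour 1 and on the centring. Without that tumour, the difference between females and males was 0.562 percentage points for lost, -0.398 for gained and -0.0151 for deeply lost probes. With all arrays centred on the mode it was 0.29, 9.66 and -0.0784 percentage points, so the deeply lost share turned direction.

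No single probe differed between the sexes with limma at an adjusted p under 0.05, and the smallest adjusted p was 0.649. At an unadjusted p under 0.05 there were 12675 probes, which fell to 6907 without male tumour 1 and rose to 18478 without female tumour 4. In 9885 probes (5.681%) all tumours of one sex lay above all tumours of the other, where chance gives 2.86%, or 4972 probes, on average. This count was made with arrays centred on the median only. Its spread over other splits of the tumours was not measured, so the excess is not a test. The probe with the smallest p had a mean of 0.475 in females and -0.856 in males (difference 1.33, limma adjusted p = 0.649), and did not pass the threshold.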

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

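The tests of array-wide bias, of the left-out readings and of female tumour 4, the counts over splits and the share of called probes at 0.2 were chosen after their results were seen. 14 groups of 4 tumours were examined for a tumour far from the others, and chance gives such a gap in about 1 in 20 groups. Female tumour 1 stood apart from the other 3 female tumours in its gained share (33.2%), its deeply lost share (2.27%) and its share of probes at or above 1 (1.26%). Of its 3948 deeply lost probes, 96.6% were deeply lost in no other tumour, and their median there was -1.09. Setting its mode to 0 lowered its deeply lost share to 0.308% and raised its gained share to 47.3%, so the deep loss excess rests on the centring. The gained excess held with the median or the mode at 0. A zero point at its upper peak of 0.49, which held 46.4% of its probes, was not tried. Whether the gained excess would hold there is therefore open. Male tumour 4 stood apart from the other males in its probes at or above 1 (0.902%). Of its 1569 such probes, 16.1% had another beside them on the array, against at most 9.18% in 100 random sets. A blemish of the array surface behind part of this group is therefore not excluded.

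Male tumour 2 stood apart from the other males in probes at or above 3 (0.0833%). Of its 145 probes, 4 (2.76%) had another such probe beside them on the array. Random sets of the same size gave 0.462% on average and 3.45% at most, and 2 of 100 gave as large a share. The other probes lay apart, which argues against a blemish of the array surface as the cause of the whole group but not of a few of its probes. That the group is a focal amplification is a hypothesis, untested without probe positions. The highest ratios of female tumour 4, up to 8.78 as deposited, differed from this. Of its 20 probes at or above 2, 55% had another beside them and no random set had any, which is consistent with a blemish of the array surface.

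Of the 782 probes deeply lost in at least 4 tumours, 3.32% had another beside them on the array, and random sets reached 6.65%. This argues against a surface defect at the same place on several arrays. A blemish of 1 array alone could not select such probes, so the share does not test it. A bias of labelling or dye of about equal size on all arrays would lower the shared deep loss set in every tumour. A median above -0.5 in any tumour was taken to exclude such an equal bias as the whole cause. The median was -1.13 or lower in 6 tumours and -0.19 in 1 tumour of each sex, which argues against an equal bias as the whole cause. The readings cannot decide on a bias whose strength differs between arrays, because such a bias could spare single tumours. A shift of the size seen in those 2 tumours is not excluded. That the set is a deletion is a hypothesis: whether its probes form 1 region, and whether the change arose in the tumours, was not tested.

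Of the 25923 lower and 24694 higher probes, most with small mean shifts, 35.6% were lost or gained the same way in at least 4 tumours at the threshold of 0.3 and 76.8% at 0.2. The first share had been set beforehand as a test of recurrent copy number change as the whole cause, but most mean shifts lie inside 0.3 (medians -0.267 and 0.257), so the threshold sets the outcome and excludes nothing. Within each of the 3 peaks of female tumour 1, its ratios correlated across probes with the mean of the other 7 tumours (r at least 0.301, and at least 0.329 among probes within 0.4 of 0 in those 7; probes are not independent replicates), which is consistent with a labelling or dye bias of the probes that the arrays share. In probes within 0.4 of 0 on all 8 arrays, pairs among the other 7 tumours correlated at 0.24 to 0.59, but pairs with female tumour 1 only at -0.02 to 0.18 when its peaks were pooled. The size of such a bias was not measured, and recurrent copy number change, in part or all of the probes, stays open.

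649 probes were above 0 in all 4 female and below 0 in all 4 male tumours, and 844 showed the opposite, a difference that was not tested. At an adjusted p under 0.05 the real split by sex gave 0 probes, as did all 35 splits of the 8 tumours into 4 and 4 (highest other 0), so a count of 0 in all of them says nothing about chance. At an unadjusted p under 0.05 the real split gave 12675 probes and the highest of the other splits 11482, so of the 35 splits only the real one was as large. With arrays centred on the mode, the real split gave 8874 probes, 3 of 35 splits, the real one included, were as large and the highest other gave 9671, so chance is not excluded under both centrings. A difference between sexes stays open and untested by an independent set of tumours.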

How the results depend on the processing

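Of 198 alternative values, 181 stayed on the same side of their threshold or within their allowed range and 17 did not. The allowed range was wide for some results. The mean gained share of 10.1% counted as unmoved at 17.9% and 3.8%, and the deeply lost share of 0.772% at 0.164%. Differences between the sexes that turned direction, such as -0.398 points for gained probes without female tumour 1, also counted as unmoved. The numbers of probes with a mean different from 0 stayed within 1.5 times, from 18693 to 35584 lower and from 17259 to 33613 higher, and the minimum difference of 0.1 moved nothing. The count for the sexes was 0 in every limma setting, with smallest adjusted p from 0.162 to 0.869, and 9885 probes lay at the smallest exact permutation p. With call thresholds of 0.2 and 0.5, recurrent losses numbered 26760 and 2679, recurrent gains 22663 and 952, the mean lost share was 19.1% and 3.91%, and the mean gained share 17.9% and 3.8%. Requiring 3 or 6 tumours gave 19412 and 4260 losses and 15452 and 1920 gains, and 6 tumours gave 240 deep losses. Leaving out 1 tumour gave 5037 to 7036 recurrent gains, the lowest without female tumour 1. Deep loss thresholds of -0.8 and -1.5 gave 1178 and 96 recurrent deep losses. The mean deeply lost share was then 1.53% and 0.164%. At -1.5 its difference between females and males was -0.0217 percentage points. A shared deep loss set defined and read at -1.5 was found in 3 tumours. Centring on the mode moved that difference to 0.29 points for lost, 9.66 for gained and -0.0784 for deeply lost probes, with exact permutation p of 0.8, 0.686 and 0.771. Looser thresholds admit more probes by construction. Alternatives for the shared sets, the 145 probes of male tumour 2 and the probes beside bright spots of female tumour 4 were chosen after seeing the data; the last left every count within 1.5 times. Settings for gene summaries, probes per gene, sex chromosomes, GC content, segmentation, neighbour noise, chromosome means and gene lists were not run, because probe positions and names were not used here. No paired analysis was possible because replicate numbers only name the tumours. What signal over background limits was not analysed here.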

Other observations

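Groups of probes changed together in the same subset of tumours more often than independent calls would give, at a log2 ratio of 0.4 in either direction. 1137 probes were gained in female tumours 1 and 2 and male tumour 4 and in no other, where 66.5 were expected. 655 probes were gained in female tumours 1 and 3 and male tumours 2, 3 and 4 and in no other, where 0.0305 were expected. 457 probes were lost in female tumours 2, 3 and 4 and male tumours 1, 3 and 4 and in no other, where 0.00206 were expected. 183 further probes were lost in the same 6 tumours and gained in female tumour 1, and 191 were lost in all 8. 364 probes were lost in female tumours 1 and 2 and male tumour 3, where 76 were expected. These expected numbers assume that calls are independent between arrays, which a probe bias shared by the arrays would break. Probes of 1 altered region also change together, so these numbers of probes are not numbers of separate changes. In female tumour 1 the upper density peak of 0.49, which held 46.4% of its probes, lies above the threshold of 0.4.

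The 3948 deeply lost probes of female tumour 1 had a median of -0.34 in female tumour 3 and between -0.16 and -0.09 in the other 6 tumours. Of the 19 probes at or above 2 in male tumour 1, 31.6% had another such probe beside them on the array, and no random set had any.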
